A study of Drosophila melanogaster with 2 samples.

How the data were processed

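Chromatin immunoprecipitation with an antibody against GFP and sequencing was done on whole embryos of a line that expresses btn with an eGFP tag, in 2 biological replicates of 1 group, per the labels. Each replicate number is the one the labels give, and the labels name a separate biosample for each. The deposited files used were 8 peak lists in narrowPeak layout, 4 in each of the builds dm6 and dm3: the candidate regions of replicate 2, of replicate 3 and of the pooled replicates, which the authors named as input for an irreproducible discovery rate (IDR) analysis, and the authors' optimal IDR-thresholded peaks.

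Per the deposited README files, each candidate list was derived from alignments and a control file, and the optimal list from the candidate lists of both replicates and of the pool. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal column of each list is the authors' deposited peak signal value, which is used here only to rank, describe or filter regions within a list. The −log10 q-value column, as deposited by the authors, has many ties at its highest value and was not used for ranking. The column before it holds -1 throughout. The summit offset, in bp from the start of the region, is another deposited column; it gave the summit position. In 1 region of the dm6 pooled list the summit lies outside the region, and it was used as given. Of the dm6 pooled candidates, 98.9% are 410 bp wide. The reads were not analysed here, no list gives a read count, and depth is therefore unknown, so no statement about sequencing error per region is made.

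Coordinates of the dm6 lists lie within the chromosome lengths of the Release 6 genome assembly, and gene models came from Ensembl release 115 (BDGP 6.54). Nothing was converted between builds. A summit was assigned to the first of these classes that held it: coding exon, 5′ UTR, 3′ UTR, noncoding exon, intron or intergenic. Because the optimal set held exactly the pooled candidates of highest signal, pooled candidates that overlap an optimal peak by at least 1 bp (2606, of which 453 are neighbours that are not optimal themselves) were called passing, and the other 27394 were the background, as they could have passed. All Fisher's exact tests were two-sided and gave conditional odds ratios. Peaks and genes are not biological replicates, and p-values measure how regions or genes divide, not how embryos vary.

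Gene lists (20) and words (15) were fixed before the data were examined, and the 100 matching draws were added afterwards. A gene counted as having a peak when a summit was within 1 kb of any of its TSSs, and the background was protein-coding genes with any pooled candidate summit within 1 kb. List members were matched by symbol or by a unique synonym (9 names); 9 names matched no gene, some of them second spellings of a listed gene (nos, Star, forked). Dl was among them, since the annotation names it Delta, so the Notch list was tested without this gene. The lists hold 414 distinct genes, of which 29 are in more than 1 list. The ribosomal protein list was taken by symbol and includes a few related genes such as RpLP0-like. Words were searched on both strands within 100 bp of the summit. Each passing candidate was matched to a candidate that did not pass by GC content rounded to 1 percent, without replacement, and mean GC was 39.4% in both sets after matching. Within optimal peaks, sequence within 50 bp of the summit and within 50 bp of a point 300 bp below it was compared by an exact McNemar test. Adjusted p-values are by Benjamini-Hochberg over the lists, the words or all words of 6 bases, with a threshold of 0.05. For the btn locus, candidate summits within 25 kb were counted and set against 1000 random windows of 3R.

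Named genes followed a rule fixed before the data were examined: btn; the gene with the nearest TSS for each of the 20 strongest optimal peaks with a candidate in both replicates; up to 4 members per list with the strongest peak within 1 kb of a TSS; and the 5 genes with most summits in the gene body or 2 kb around it. Any other named gene was chosen after its values were seen. Words named were the 15 fixed ones and the 5 words of 6 bases with the lowest p.

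The word and list tests were tested on simulated data first. With TAATTA placed in 10% of 2606 simulated peaks, 100 of 100 runs passed at p under 0.05 with a median odds ratio of 1.78, and with none placed 5 of 100 did. A list of 88 genes with a planted odds ratio of 5 was called in 100 of 100 runs, and a list of 20 genes in 68 of 100; lists with no planted effect were called in 0 of 100 runs at either size.

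Alternatives were the upper part of the optimal peaks by signal (at or above their median), the strongest 2153 candidates of each replicate used alone, other distances to the TSS, other backgrounds, other windows for words, no GC matching, overlap of at least 50% of both regions, other numbers of top regions, other windows at btn, and dm3. For a replicate used alone, its own remaining candidates were the background. An alternative was counted as turning a direction only if the value was past the threshold on at least 1 side of the change. The dm3 lists entered only where no annotation or sequence is needed. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.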

Results

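The series set out to map the genomic regions bound by Buttonless (btn), a homeodomain protein of Drosophila melanogaster. Whole embryos of mixed sex were collected 0 to 14 hours after egg laying. No untagged line was analysed here, so the peaks are not shown to be bound by btn itself. The embryos came from a transgenic line that carries btn with an enhanced green fluorescent protein (eGFP) tag at its C-terminus, and chromatin was recovered with an antibody against GFP after sonication to fragments of 200 to 800 bp. There was 1 group with 2 biological replicates, called replicate 2 and replicate 3 as the labels number them. No other condition, stage or genotype was analysed here, so the comparisons set peaks against weaker candidate regions, the replicates against each other, and gene groups against other genes. The number of reads per library is not given in the sources used here, so depth is unknown, and the intervals below describe counts of regions or genes only. Positions are in the dm6 build, counted from 1.

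The peak set that passed the authors' reproducibility threshold, called optimal peaks here, held 2153 regions in dm6. They were the 2153 strongest of the 30000 pooled candidate regions, which is 7.18% of them. The weakest optimal peak had a signal of 70.5 and the strongest 1220, where signal is the authors' own peak value, used here only to rank regions within a list. The strongest peak lay in an intron of px (plexus, a wing vein patterning gene; 2R 22514107 to 22514500), 203 bp upstream of a transcription start site (TSS). The next was at the TSS of Ugalt, a UDP-galactose transporter gene (X 2703686 to 2704082, signal 1194), and the third was in an intron of ush (u-shaped, a cofactor of GATA factors), 1387 bp upstream of a TSS of cbt (cabut), with a signal of 1116.

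Others of the 20 strongest peaks lay in or near named genes of several kinds. A peak in the 5′ UTR of Chro (Chromator, a chromosomal protein of interband regions) had a signal of 868, and a peak in an intron of ph-p (polyhomeotic proximal, a Polycomb group gene) had a signal of 833. A peak in an intron of the kinase gene Lk6 reached 794, and a peak 3158 bp upstream of tara (taranis) reached 732. A peak in an intron of cno (canoe, an adherens junction protein) reached 629. The rest of the 20 strongest peaks had CG14100, CG11050, PNPase, CG1888, CenG1A, hll, Art3, CG13323, CG9147, CG13921, CG4004 and CG9663 as the nearest protein-coding gene, with signals from 560 at CG9663 to 1003 at CG14100. Some of these genes are far from their peak: the TSS of CG13323 was 11908 bp away and that of CG4004 was 5118 bp away.

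Several long genes held many peaks. kirre, which encodes an adhesion protein of muscle founder cells, had 12 optimal summits in its body or within 2 kb of it. Raf, a kinase gene of the EGFR pathway, had 10, and sbb (scribbler) had 9. Eip75B and Hr4, nuclear receptor genes of the ecdysone response, had 8 each, as did shn (schnurri, a cofactor of BMP signalling), ush and CG1677. These 5 genes were tied, and all are named although the rule for naming took only 2 of them. Gene length differed widely in this group, from 48405 bp for Raf to 394149 bp for kirre, and the counts are not scaled to it.

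Both replicates ranked the same regions first. All of the 20 strongest optimal peaks overlapped a strong candidate in each replicate: px ranked 2 in replicate 2 and 1 in replicate 3, Ugalt ranked 1 and 2, cbt ranked 3 in both, and CG14100 ranked 4 in both. Of the 2153 strongest candidates of replicate 2, 1529 overlapped by at least 1 bp a region among the 2153 strongest of replicate 3, a share of 71.0% (exact 95% interval 69.0 to 72.9%). Regions of replicate 3 shuffled within chromosomes gave a median of 1.25% and a maximum of 2.09% in 1000 shuffles (one-sided permutation p = 0.000999, the smallest that 1000 shuffles can give). Across the 2152 optimal peaks with a candidate in both replicates, signals of the replicates had a Spearman rho of 0.653 (approximate 95% interval 0.627 to 0.677) and a Pearson r of log2 signal of 0.763. Peaks are not independent replicates, and the optimal peaks were selected from both libraries together, which shapes the range over which rho was taken.

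**Figure D1:**
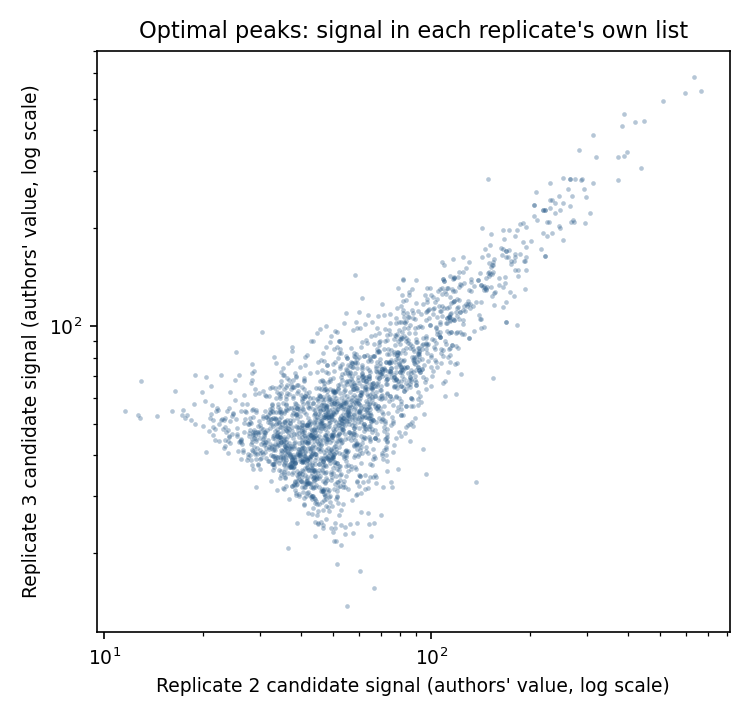
Signal of each optimal peak in the candidate list of replicate 2 (x axis) and of replicate 3 (y axis), both the authors' values on log scales; each point is 1 of the 2152 peaks with a candidate in both. The points rise together, with a Spearman rho of 0.653.

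Optimal peaks lay at promoters, in introns and between genes, and hardly ever in coding sequence. Candidates that overlapped an optimal peak (2606 regions, called passing) had their summit within 1 kb of a protein-coding TSS in 56.4% of cases, against 38.0% of the 27394 candidates that did not pass. The odds ratio was 2.11 (95% interval 1.95 to 2.30, two-sided Fisher's exact p = 1.27e-73). The median distance from an optimal summit to a TSS was 672 bp, against 1708 bp for candidates that did not pass, and 20.1% of optimal summits were within 100 bp of a TSS, against 8.78%. Introns held 48.4% of passing summits against 36.0% (odds ratio 1.67, exact test, adjusted p = 1.24e-34). Intergenic sequence held 33.3% against 22.0% (odds ratio 1.76, exact test, adjusted p = 1.87e-35), and 5′ UTRs 12.1% against 7.88% (odds ratio 1.61, exact test, adjusted p = 2.05e-12).

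Coding exons showed the largest difference between the classes tested. Only 40 of 2606 passing summits (1.53%) were in a coding exon, against 7950 of 27394 (29.0%), an odds ratio of 0.0381 (95% interval 0.0271 to 0.0521, Fisher's exact p = 4.87e-297). Summits in 3′ UTRs were also less frequent among passing candidates, at 1.27% against 2.34% (odds ratio 0.535, exact test, adjusted p = 0.00027). Sequence within 100 bp of the summit had a GC content of 39.4% ± 7.37 (SD, n = 2606) in passing candidates and 47.0% ± 9.64 (SD, n = 27394) in the others. With summits shuffled within chromosomes as background instead of candidates, the promoter odds ratio was 5.07, over 1.5 times the main value.

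**Figure D2:**
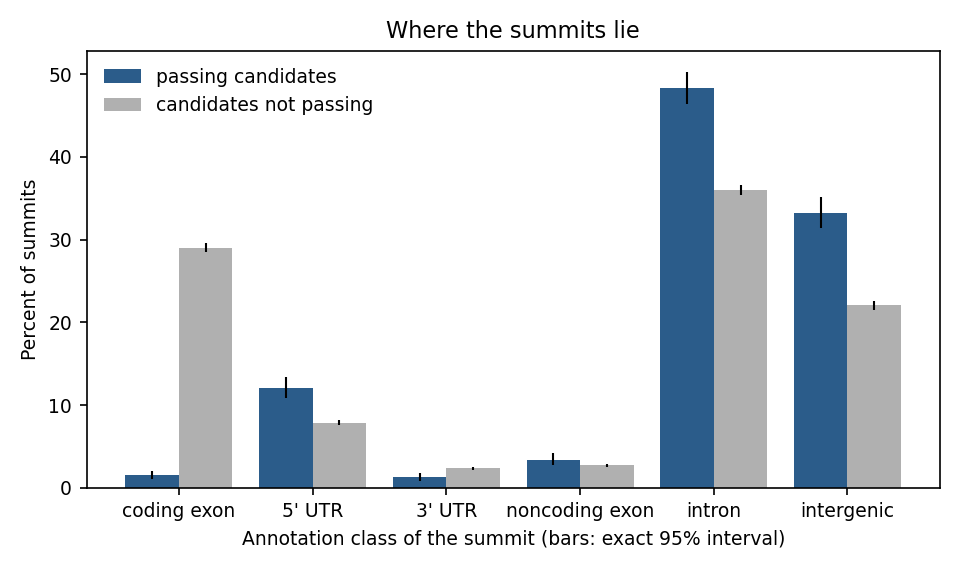
Percent of summits (y axis) in each annotation class (x axis) for the 2606 passing candidates and the 27394 candidates that did not pass; error bars are exact 95% intervals. Coding exons hold 1.53% of passing summits and 29.0% of the others, while introns and intergenic sequence hold larger shares of the passing ones.

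The X chromosome held a slightly larger share of passing candidates than of the rest. On X were 470 of 2606 passing candidates (18.0%) and 15.6% of those that did not pass (odds ratio 1.19, 95% interval 1.07 to 1.32, Fisher's exact p = 0.00151). Chromosome 4 held 9 of 2606 (0.345%) against 0.694% (odds ratio 0.496, exact test, adjusted p = 0.0358). The difference on X was not past the threshold when replicate 3 was used alone (odds ratio 1.06, exact p = 0.310) or against chromosome lengths (odds ratio 1.03, binomial p = 0.537). X makes up 17.6% of the assembled length of the main arms.

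Ribosomal protein genes stood out among the gene groups. Of 8662 protein-coding genes with any candidate summit within 1 kb of a TSS, 1511 (17.4%) had an optimal one. Genes for cytoplasmic ribosomal proteins had one in 52 of 88 cases (59.1%) against 17.0% of other genes, an odds ratio of 7.04 (95% interval 4.50 to 11.1; Fisher's exact test, Benjamini-Hochberg adjusted p = 3.12e-17 over 20 lists). The strongest of these peaks were at RpL7 (2L 10200917 to 10201159, signal 390, 45 bp from the TSS), RpS27 (signal 343, 7 bp), RpL13A (signal 269, 55 bp) and RpL14 (signal 266, 23 bp). Each of these 4 peaks overlapped a candidate in both replicates. The list was past the threshold under every alternative run for it, single replicates included, with odds ratios from 5.58 (without replicate 3) to 10.8 (all protein-coding genes as background).

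Genes of the EGFR, Notch and BMP signalling pathways were not past the threshold at promoters in the main analysis. Of 15 EGFR pathway genes in the background, 7 had an optimal summit within 1 kb of a TSS (odds ratio 4.15, 95% interval 1.28 to 13.1, exact test, adjusted p = 0.0848), among them spi (spitz, the EGFR ligand; signal 273), Raf (214), aop (anterior open, a transcriptional repressor; 112) and Ras85D (105). The EGFR odds ratio was 2.04 without replicate 2, 2.31 without replicate 3 and 2.02 with a TSS within 500 bp, and it passed with a TSS within 2 kb (8 of 16, odds ratio 4.45, exact test, adjusted p = 0.0273). The Notch pathway had 7 of 20 (odds ratio 2.56, exact test, adjusted p = 0.359), with gro (groucho, a corepressor; signal 277), nej (nejire, the CBP acetyltransferase; 162), E(spl)m7-HLH (128) and numb (83.1); Delta, the Notch ligand gene, is not in the list because its fixed name matched no gene. The Notch odds ratio was 4.01 without replicate 2, 1.54 without replicate 3 and 1.52 with a TSS within 500 bp, and it passed with a TSS within 2 kb (11 of 20, odds ratio 5.44, exact test, adjusted p = 0.00261). The BMP pathway had 4 of 12 (odds ratio 2.37, exact test, adjusted p = 0.374), namely Mad (the pathway's Smad; signal 328), shn (213), brk (brinker, a repressor; 100.3) and cv-2 (75.8), and 2 of 12 with a TSS within 500 bp (odds ratio 0.908). With all protein-coding genes as background, the EGFR list (odds ratio 5.79, exact test, adjusted p = 0.0125) and the Notch list (4.45, adjusted p = 0.0248) passed. The BMP list did not (3.00, exact test, adjusted p = 0.282). Several Notch genes with a peak lie in 1 gene complex, Enhancer of split, and the tests count them as separate genes.

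When a summit anywhere in the gene body or within 2 kb of it was counted, 13 of 17 EGFR, 10 of 13 BMP and 12 of 20 Notch pathway genes had an optimal one, against 22.7% of other genes in each case, with odds ratios of 11.1, 11.3 and 5.10 (exact test, adjusted p = 4.05e-05, 0.000356 and 0.00187). Of the 12 Notch genes, 6 belong to the Enhancer of split complex, and E(spl)m8-HLH shares its strongest peak with gro. All tests here count such neighbours as separate genes, so the Notch calls rest in part on 1 gene complex. Under that assignment 6 lists were past the threshold rather than 1. The others were genes of the CNS midline and of dorsal median cells, the cells in which btn is expressed (13 of 24, exact test, adjusted p = 0.0033), glial genes (7 of 11, exact test, adjusted p = 0.0145) and the ribosomal protein genes (55 of 88). These lists share genes with a peak: spi, pnt, aos and vn are in the EGFR and midline lists, and pnt and wrapper in the midline and glial lists. The EGFR, midline and glial calls are therefore not independent of each other. With gene length and TSS number as covariates, an addition made after seeing the data, the EGFR, BMP, Notch and ribosomal protein lists were past the threshold with odds ratios of 7.23, 7.86, 5.19 and 7.52, the germline list was past it on the lower side, and the midline and glial lists were not (likelihood-ratio chi-square test of a logistic model, adjusted p = 0.0591 for both). Whether a list differed between the assignments was not tested.

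Few patterning genes had an optimal peak at their promoter, and no patterning list differed from other genes by the test. None of 15 pair-rule and segment polarity genes, 12 epidermis and cuticle genes and 9 germline genes had one (exact test, adjusted p = 0.359, 0.538 and 0.656). Their upper 95% limits of the odds ratio were 1.32, 1.70 and 2.40. The first and second of these counts depended on the library: without replicate 2 they were 1 of 14 and 1 of 12, with upper limits of 2.30 and 2.81, and without replicate 3 the pair-rule list had 1 of 19. Of the Hox complex, 1 of 8 had one, bcd (bicoid, the anterior determinant; signal 119), and of the gap and head gap genes 1 of 10, cnc (110). Mesoderm and muscle identity genes had 3 of 29, namely org-1 (signal 131), mbc (113) and tup (70.6), and 5 of 26 without replicate 3 (odds ratio 1.10 in place of 0.545). With gene bodies and 2 kb around them counted, pair-rule and segment polarity genes had 6 of 20, Hox 4 of 11 and mesoderm 13 of 35. Epidermis and cuticle genes then had 5 of 14, gap and head gap genes 2 of 14 and germline genes 0 of 13. Of other genes 22.7 to 22.8% had one, and by the exact test none of these lists was past the threshold.

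Midline, neural and glial lists gave the following at promoters, none past the threshold. The CNS midline and dorsal median cell list had 3 of 21, which were spi, Ama (amalgam; signal 102) and comm (commissureless, which controls midline crossing of axons; 71.4). Neuroblast and neuronal fate genes had 6 of 30, led by brat (brain tumor; signal 257), lola (144), elav (133) and pros (prospero; 88.7). Neuronal differentiation genes had 2 of 13, elav and Fas2 (92.7). Glial genes had 4 of 10, which were moody (a receptor of the blood-brain barrier; signal 219), Gs2 (glutamine synthetase 2; 160), nrv2 (83.8) and Gli (80.6). Without replicate 2 the glial list had 3 of 12 in place of 4 of 10 and the neuronal differentiation list 3 of 12 in place of 2 of 13, each a change of the odds ratio by over 1.5 times, and without replicate 3 the midline odds ratio was 0.512 in place of 0.788.

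The remaining tissues and responses had no list past the threshold either. Muscle structural genes had 4 of 21 (Msp300, sls, mys and if, with signals of 166, 143, 89.5 and 83.5). Hemocyte and fat body genes had 2 of 7 (ush at 100.04 and LanA at 71.4), tracheal genes 3 of 8 (bnl at 119, sty at 94.3 and rib at 82.4), and endoderm and gut genes 3 of 10 (fkh at 235, bowl at 150.1 and peb at 70.6). Ecdysone response genes had 3 of 14 (Eip75B at 215, Hr39 at 77.1 and Hr3 at 75.7). Heat shock genes had 4 of 12 (Hsp27 at 277, Hsp83 at 276, Hsp26 at 100.2 and Hsc70-3 at 76.3). Several of these lists moved by more than 1.5 times without replicate 3: the tracheal odds ratio from 2.84 to 0.576, the hemocyte one from 1.89 to 0.576, the endoderm one from 2.03 to 1.03 and the ecdysone one from 1.29 to 0.419. The ecdysone odds ratio was 2.25 without replicate 2.

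**Figure D3:**
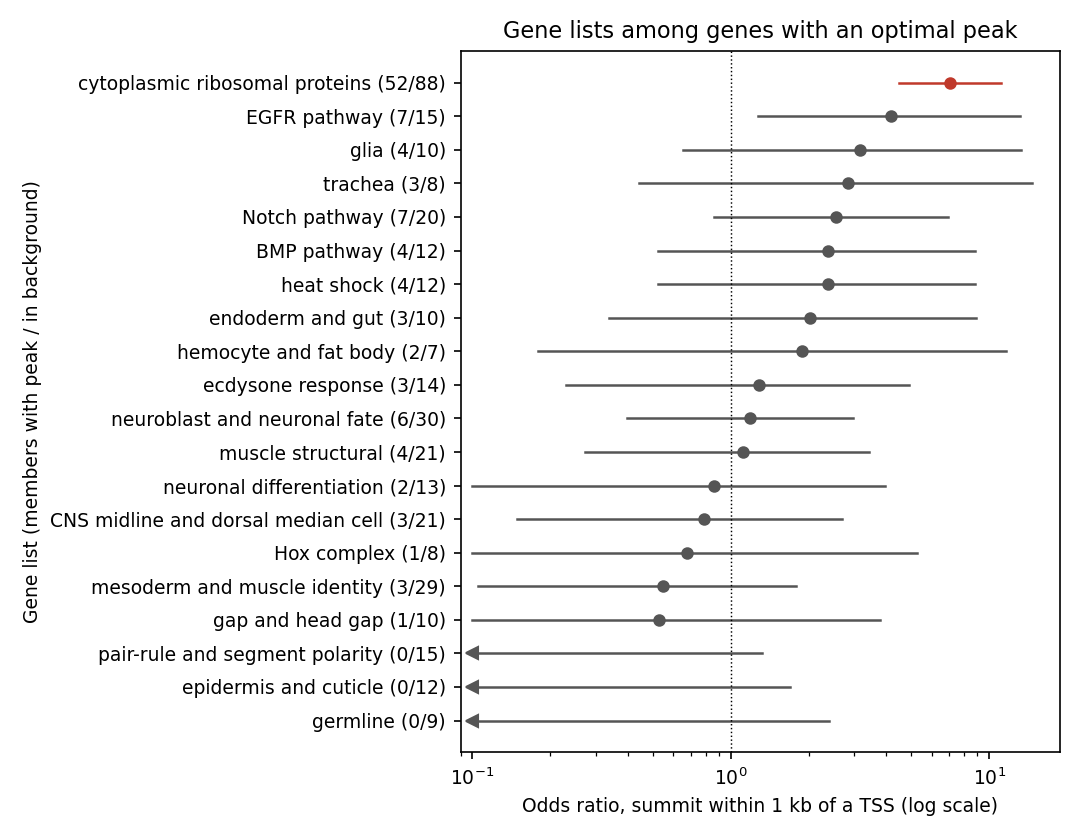
Odds ratio (x axis, log scale) of having an optimal summit within 1 kb of a TSS for each of 20 gene lists (y axis), with its 95% interval drawn as a line that is cut at the left edge; red marks an adjusted p under 0.05 and an arrow an odds ratio of 0. The cytoplasmic ribosomal protein genes, at 7.04, are the only list in red.

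The homeodomain core word was not more frequent at btn-eGFP peaks than at weaker candidates of the same GC content. TAATTA, the site that many homeodomain proteins of the Antennapedia class bind, was within 100 bp of the summit in 12.6% of passing candidates and in 13.9% of an equal number of GC-matched candidates that did not pass (odds ratio 0.896, 95% interval 0.760 to 1.05, Fisher's exact adjusted p = 0.319 over 15 words). The 2 control words of the same base composition, ATTAAT and TTATAA, had odds ratios of 1.03 and 0.910. The wider homeodomain word TAATKR was less frequent in passing candidates, at 39.8% against 45.6% (odds ratio 0.788, exact test, adjusted p = 0.000175), and so was the composite Exd-Hox word TGATNNAT, in 11.5% of passing candidates (odds ratio 0.732, adjusted p = 0.000842). Over 100 draws of matched candidates, these words were past the threshold in 94 and 83 draws and TAATTA in 6; TGATNNAT lost its call without replicate 2 (odds ratio 0.931). Without GC matching the TAATTA odds ratio was 1.49, the opposite direction, in a background with the higher GC content given above.

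Other words marked the passing candidates. The GAGA repeat GAGAGAG was in 6.02% against 2.99% (odds ratio 2.08, exact test, adjusted p = 2.25e-06) and was past the threshold in 100 of 100 draws. The DNA replication-related element TATCGATA, found at housekeeping promoters, was in 71 against 39 of 2606 (odds ratio 1.84, exact test, adjusted p = 0.00996), a call that depended on the draw: it was past the threshold in 37 of 100 draws (median odds ratio 1.56) and not with either replicate left out (1.44 without replicate 2, 1.42 without replicate 3). Within 50 bp of the summit TATCGATA was in 44 against 10 (odds ratio 4.46, exact test, adjusted p = 2.27e-05). It also passed within 200 bp (1.56) and outside coding exons (1.61), but not in the upper part of the peaks by signal (1.68). Draws were not repeated for these alternatives. The CTCF core AGRKGGC was in 241 against 190 of 2606 (exact test, adjusted p = 0.0355), in 91 draws, and lost its call without replicate 2 (odds ratio 1.09), in the upper part of the peaks by signal (1.27) and within 50 bp of the summit (1.32). The CACACACA repeat, the Zelda site, Motif 1, the Twist E-box, CAGCTG, the GATA site and the Mef2 site were not past the threshold, with the highest odds ratio, 1.37, for the CACACACA repeat, which passed without replicate 2 (exact test, adjusted p = 0.0418) and in the upper part of the peaks by signal (adjusted p = 0.0261), and in 11 of 100 draws. CAGCTG passed in 25 of 100 draws, within 200 bp of the summit (odds ratio 1.36, exact test, adjusted p = 8.02e-05) and outside coding exons (adjusted p = 0.0441). Among candidates beyond 1 kb of a TSS, 1135 on each side, none of the 15 words was past the threshold: GAGAGAG was in 52 against 39 (odds ratio 1.35, exact test, adjusted p = 0.373), and TAATKR and TGATNNAT had odds ratios of 0.813 and 0.768 (exact test, adjusted p = 0.138 for both). The shorter word AGAGAG, tested there after seeing the data, was in 145 against 95 (odds ratio 1.60, exact test, p = 0.000796). The result for GAGAGAG therefore does not show that GA repeats mark only promoters.

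Of all strand-merged words of 6 bases, 43 were more frequent and 44 less frequent in passing candidates at an adjusted p under 0.05, and TAATTA ranked 727 by p. The word with the lowest p was ACAGTG, in 521 against 299 of 2606 (odds ratio 1.93, 95% interval 1.65 to 2.26, Fisher's exact adjusted p = 6.01e-14). AGAGCG (odds ratio 1.84), GAGAGC (1.81), AGAGAG (1.69) and GTACAC (1.77) followed. With coding exons left out of both sets, an alternative added after seeing the data, ACAGTG had an odds ratio of 1.76 and again the lowest p (exact test, adjusted p = 4.78e-10).

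Within optimal peaks, TAATTA was more frequent at the summit than at the flank. It was within 50 bp of the summit in 7.25% of peaks and within 50 bp of a point 300 bp below it in 4.92% (149 peaks with the word at the summit only, 99 at the flank only, ratio 1.51, exact McNemar adjusted p = 0.00541). The control words had ratios above 1 as well, ATTAAT with a ratio of 1.31 (exact test, adjusted p = 0.0722) and TTATAA with 1.48 (adjusted p = 0.00885). The ratio of TAATTA was no longer past the threshold without replicate 2 (1.36, exact test, adjusted p = 0.0577) or against the flank on the other side (exact test, adjusted p = 0.0801). The element TATCGATA had the highest ratio of the 15 words, with 0.511% at the flank and 1.67% at the summit (ratio 3.5, exact test, adjusted p = 0.00124), and the Mef2 word had a ratio of 1.65 (adjusted p = 0.00556). The GATA word had a ratio of 1.44 (exact test, adjusted p = 4.93e-05). GC content was lower at the summits than at the flanks, at 37.3% against 44.0%. The 36 strand-merged words of A and T alone, as long as TAATTA, had a median ratio of 1.68. The ratios of the Mef2 and GATA words did not exceed that median. Neither word was set against others of its own base composition, so base composition is not excluded for their ratios. GAGAGAG and CACACACA were more frequent at the flank, with ratios of 0.605 and 0.326 (exact test, adjusted p = 0.0119 and 1.44e-07). Without replicate 2 the Mef2 word (ratio 1.33), TTATAA (1.4) and GAGAGAG (0.770) were not past the threshold, and Motif 1 was (3.83). AGRKGGC was past it without replicate 3 (1.51).

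**Figure D4:**
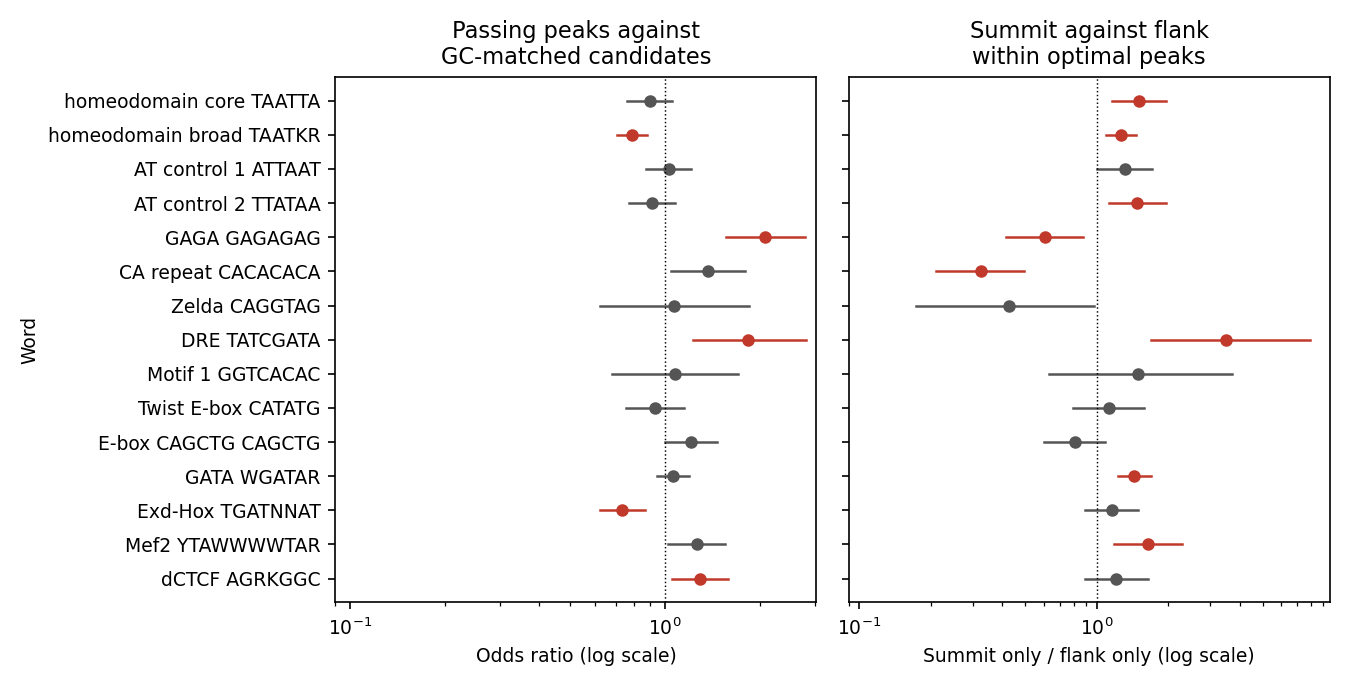
Odds ratio of each of 15 words (y axis) in passing against GC-matched candidates (left, x axis on a log scale) and ratio of optimal peaks with the word at the summit only to those with it at the flank only (right, log scale); lines are 95% intervals and red marks an adjusted p under 0.05. TAATTA lies at 0.896 on the left and at 1.51 on the right, beside its control words.

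The btn gene itself (3R 22586149 to 22586625, minus strand) had no optimal peak at its TSS, and a cluster of weaker candidates around it. The nearest pooled candidate summit was 64 bp from the TSS, with a signal of 29.0. The 2 optimal peaks within 25 kb were both in introns of the neighbouring gene Efa6, at 22590589 to 22590998 (signal 113, 4169 bp from the btn TSS) and 22597544 to 22597953 (signal 93.4, 11124 bp). The pooled list held 30 candidate summits within 25 kb of btn (exact Poisson 95% interval 20.2 to 42.8), against a median of 11 in 1000 random windows of 3R of the same length, which placed it at percentile 97.8. Among 3421 windows centred on protein-coding genes of 3R, an alternative added after seeing the data, the median was 16 and the percentile 96.7. Replicate 3 had 32 (21.9 to 45.2; median 10, percentile 98.2) and replicate 2 had 22 (13.8 to 33.3; median 12, percentile 90.7). Within 10 kb of btn the pooled list held 20 against a median of 4.

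**Figure D5:**
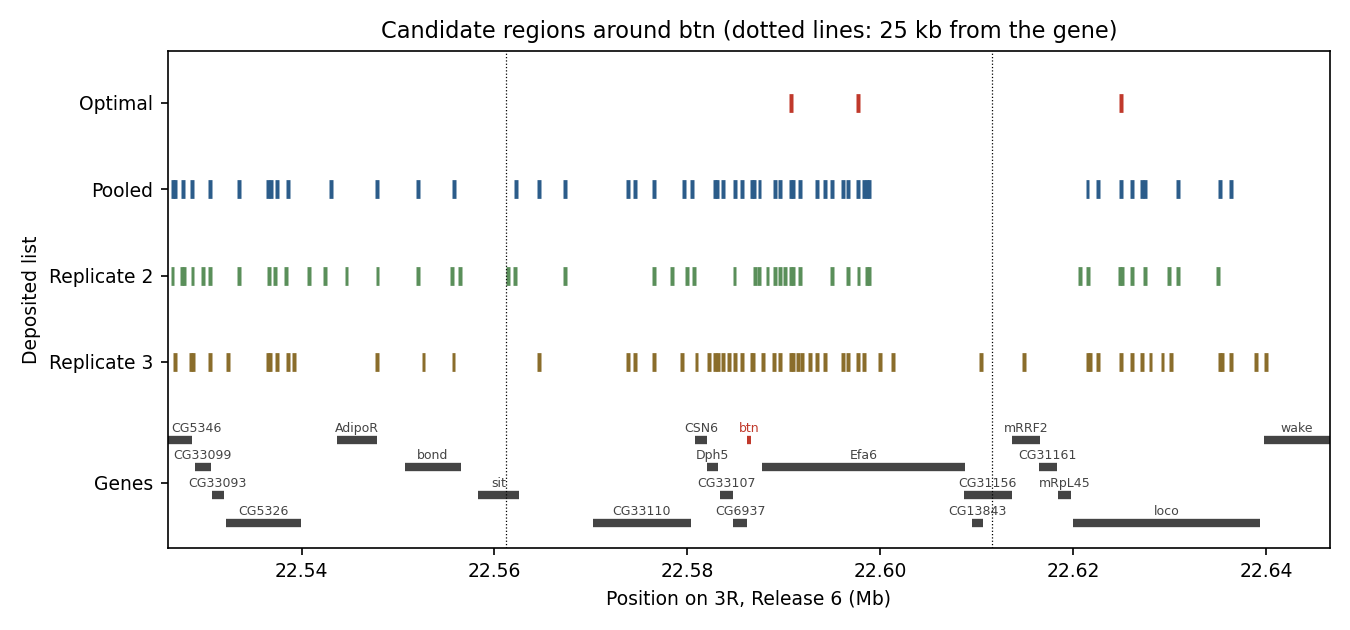
Candidate regions of each deposited list (y axis) around btn on 3R (x axis, Release 6 position in Mb), drawn to scale with the protein-coding genes below and dotted lines 25 kb from the gene. Between the dotted lines lie 30 pooled candidates and 2 optimal peaks, both inside Efa6.

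The dm3 lists gave nearly the same numbers. The optimal set had 2146 peaks in dm3 and 2153 in dm6, and the overlap of the strongest regions of both replicates was 71.3% in dm3. Genes and words were not assigned in dm3, since no dm3 annotation or sequence was used here.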

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

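All tests in this part were chosen after the main results had been seen. The bounds of those on ribosomal protein genes, TAATTA and btn were set before each test was run. Related values were already known, however: the ratios of the control words, the peak of Hsp83, the map around btn and its percentile among 3R genes.

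Most comparisons used dm6, where 1 pooled candidate, 2 of replicate 2 and 0 of replicate 3 lay off the main chromosome arms. More lay off these arms in dm3. The dm3 lists name heterochromatic sequences such as 3LHet apart from the arms, whereas the dm6 lists name only the arms and Y. The counts off the arms are therefore not comparable between builds, and few such counts in dm6 do not mean few heterochromatic candidates. In the dm3 lists, replicate 2 had 127 candidates of 29640 (0.428%, exact 95% interval 0.357 to 0.510%) on heterochromatic or unplaced sequences, replicate 3 had 20 of 30000 (0.0667%) and the pooled list 41 of 29438 (0.139%). The share was higher in replicate 2 than in replicate 3 (odds ratio 6.45, 95% interval 4.00 to 10.9, Fisher's exact p = 1.16e-20), a comparison of these 2 lists. In replicate 2, 41 of these candidates lay on 3LHet, 36 on 3RHet and 29 on 2RHet. None of the 2146 dm3 optimal peaks lay there, and the highest signal among the pooled candidates there was 42.9, below the lowest optimal signal of 70.3. No explanation was tested.

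Ribosomal protein genes carried optimal peaks with an odds ratio of 7.04. A candidate technical explanation is that chromatin of heavily transcribed genes is recovered in such experiments whatever the tagged protein. An added list of 37 other abundantly transcribed genes in the background was written by name before it was tested, with no expression measured here. An optimal summit was present in 15 (40.5%), an odds ratio of 3.25 (95% interval 1.56 to 6.57, Fisher's exact p = 0.000786). That interval overlaps the one of the ribosomal protein genes, as that explanation needs, although 3.25 itself is below their lower limit of 4.50. The 15 included eEF1gamma, Hsp83 and Act5C, and the peak of Hsp83 was already known from the heat shock list. Of the 15, the peak of 14-3-3zeta is also that of RpLP0-like, and Fer1HCH and Fer2LCH share 1 peak. Mitochondrial ribosomal protein genes, a class of housekeeping genes, had an optimal summit in 8 of 57 (odds ratio 0.771, 95% interval 0.315 to 1.65). That interval lies below the one of the cytoplasmic genes, which argues against a like preference for this class. Its strongest peaks, at mRpS23 (signal 704) and mRpS10 (655), are those named above for CenG1A and Art3. Housekeeping promoters in general were not tested. Binding of btn at these genes stays open, as no other tagged protein and no untagged line was analysed here.

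TAATTA rose from flank to summit with a ratio of 1.51. Base composition could account for it, since the GC content was 37.3% ± 9.12 (SD, n = 2153) at the summits and 44.0% ± 9.66 at the flanks. Among all 36 strand-merged words of 6 bases made of A and T alone, TAATTA ranked 28, at percentile 22.9 of the others, and their median ratio was 1.68. The rise of TAATTA was therefore no larger than that of other such words, and no biological explanation was tested.

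Candidates clustered around btn, 30 in the pooled list within 25 kb. The btn window held 9 TSSs against a median of 12 at 3R genes, which argues against gene density as the reason it was high among windows on these genes. Among 882 such windows with a similar number of TSSs, whose median was 14 candidates, it was at percentile 98.4. The exact 95% interval (97.4 to 99.1) reaches below the bound set for excluding gene density. However, this interval treats overlapping windows as independent, so it cannot settle the question. The TSSs of random windows were not counted, so gene density is not decided for the comparison with those. That the interval and not the value alone must pass the bound was required after the value was seen. Extra copies of the locus in the transgenic line could add reads there. Candidate density within 15 kb of btn against 25 to 50 kb away was at percentile 76.5 among 3R genes in replicate 2 and 86.4 in replicate 3, so neither replicate stood out enough to decide, and without copy number these explanations cannot be told apart from binding of btn near its own gene.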

How the results depend on the processing

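Alternatives added after seeing the data were the optimal peaks alone, a background outside coding exons, another matching draw, gene-centred windows, single replicates at btn, 100 matching draws, and the gene body with covariates. Of the alternatives for the results that answer a comparison, 34 of 50 changed no call or stayed within the spread, 11 moved by more, 4 lost their call and 1 turned in direction. The promoter odds ratio kept its direction and side of the threshold under each of its alternatives, from 1.76 (TSS within 2 kb) to 5.07. Of the other results, 327 kept their side of the threshold, some with a change of direction between values that were not past it, 24 passed the threshold where the main value had not, 22 no longer did and 8 turned in direction. Read depth is unknown, so how far it limits each value is too.

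The overlap of the strongest regions was 66.9% with 50% reciprocal overlap, 75.5% for the upper part by rank and 62.7% for the list of double length. The rank correlation between replicates was 0.546 with reciprocal overlap and 0.689 in the upper part by signal. The X odds ratio lost its call against chromosome lengths (1.03) and ranged from 1.06 to 1.29 with either replicate left out. The number of lists called as enriched was 1 in the main analysis, 3 with a TSS within 2 kb, 3 with all protein-coding genes as background, 6 with gene bodies and 4 with gene bodies and covariates, where the germline list was called as depleted. The summit ratio of TAATTA was 1.30 with the flank on the higher side and 1.36 to 1.66 with either replicate left out. The ratio of candidates at btn to the random median, 2.73, was 5 within 10 kb and 1.83 to 3.2 with either replicate left out. For these, the cause was not tested.

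Without GC matching, words turned in direction: TAATTA 1.49, TAATKR 1.32, TTATAA 1.70, CATATG 1.41, CAGCTG 0.809, TGATNNAT 1.13 and AGRKGGC 0.955, since the unmatched background had the higher GC content. TATCGATA was 0.499 beyond 1 kb of a TSS and the midline list 4.02 with gene bodies; the cause was not tested. No paired analysis was possible because there was only 1 group.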

Other observations

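All tests in this part were chosen after the main results were seen.

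Genes for small nuclear RNAs, the RNA components of the spliceosome and of related particles, carried optimal peaks. Summits within 500 bp of 1 of the 32 annotated snRNA genes made up 8 of 2606 passing candidates and 14 of 27394 others (odds ratio 6.02, 95% interval 2.19 to 15.4, Fisher's exact adjusted p = 0.000843 over 5 classes). The genes included snRNA:U1:95Ca (signal 112), snRNA:7SKa (110), snRNA:U1:21D (108) and snRNA:U2:34ABb (106). Genes for small nucleolar RNAs had 14 against 68 (odds ratio 2.17, exact test, adjusted p = 0.0262). Genes for other noncoding RNAs had 244 against 1886 (odds ratio 1.40, exact test, adjusted p = 3.09e-05). Coding exons held 29.0% of the background summits and 1.53% of the passing ones, and intergenic sequence had an odds ratio of 1.76. The RNA classes were not tested with coding exons left out. Summits at promoters of protein-coding genes were not left out either. The ratios of small nucleolar and of other noncoding RNAs are therefore not shown to be particular to these genes. Transfer RNA genes had 7 against 108 (odds ratio 0.680, 95% interval 0.267 to 1.45, exact adjusted p = 0.508) and pseudogenes 6 against 54 (odds ratio 1.17, exact adjusted p = 0.646).

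Genes in this paragraph were chosen after their counts were seen. Summits were counted in the gene body and 2 kb around it, so neighbouring genes can share one: gro and E(spl)m8-HLH have the same strongest peak (signal 277). In the EGFR list, Raf had 10 optimal summits, aop 4, spi 3 and edl 3. In the BMP list, shn had 8 and cv-2 3, and dpp, tkv, Dad, Med and gbb had 1 each. In the Notch list, 6 genes of the Enhancer of split complex had at least 1 summit, with 2 each for E(spl)m7-HLH and E(spl)m8-HLH, and N itself had 2. In the ecdysone list Hr3 had 4 and EcR 3 beside the 8 of Eip75B and of Hr4. The germline list had none among its 13 genes.

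The word ACAGTG, first by p over the whole genome, was also first when only chromosomes 2, 4 and X were searched. On chromosome 3, which took no part in that search, it was in 18.4% of 1110 passing candidates and 11.4% of matched ones. The odds ratio was 1.74 (95% interval 1.36 to 2.23, Fisher's exact p = 5.49e-06, adjusted p = 0.0114). Other leading words of that search kept their direction on chromosome 3 but were not past the threshold there. AGAGCG had an odds ratio of 1.48 (exact test, adjusted p = 0.344) and ACACTG 1.46 (adjusted p = 0.131). AGAGAG had 1.32 (exact test, adjusted p = 0.557) and CAGGAG 0.720 (adjusted p = 0.741). Over all chromosomes, the odds ratio of ACAGTG was 1.73 (1.41 to 2.14) within 1 kb of a TSS and 2.23 (1.75 to 2.84) beyond. Within optimal peaks it was in 8.73% of summit windows and 4.64% of flank windows (ratio 2.05, 95% interval 1.57 to 2.69, exact McNemar p = 4.01e-08). AGAGAG, another leading word, was more frequent at the flank (ratio 0.747, 95% interval 0.583 to 0.954). Its odds ratio in passing candidates was 1.95 (1.54 to 2.49) within 1 kb of a TSS and 1.60 (1.21 to 2.13) beyond. Which protein binds ACAGTG was not tested.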
